A study of Mus musculus with 15 samples.

How the data were processed

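Total RNA was taken from brain homogenates of 15 mice with a column kit for fatty and fibrous tissue, and stranded mRNA libraries were made with a TruSeq kit, per the labels' protocols. The libraries were sequenced as 150-bp paired-end reads on a NovaSeq instrument, per the series description. The part of the brain that was homogenised, the age of the mice and the dose of peptide are not given in the sources used here. The groups were wild type (n = 4), Tg-SwDI given PBS (n = 5) and Tg-SwDI given D4F (n = 6), with 1 library per mouse.

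Reads were trimmed with Trimmomatic, aligned with HISAT2 to GRCm38 and counted per gene with featureCounts, per the submitters' processing notes. Program versions, the annotation release, the strand setting and the rule for reads that map to several places are not given in the sources used here. The deposited values are raw counts per Ensembl gene, whole numbers with no normalisation, per the file headers. Their column sums equal the library sizes stated in the file header in 15 of 15 libraries. Gene symbols, chromosomes and coordinates were taken from the count table itself. Of its 55487 gene IDs, 99.5% were found in GENCODE M21, and 99.4% had the same start and end there. Reads from the human part of the transgene have no gene of their own in a mouse annotation, so transgene expression was not measured as such.

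Library totals ranged from 25618248 to 36333318 counts. Genes were kept by the edgeR function filterByExpr by group, which left 18736 genes. Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, with all 15 libraries in 1 fit and with terms for group and sex. The contrasts were Tg-SwDI PBS against wild type, D4F against PBS, D4F against wild type, and female against male. The differences of the transgene effect and of the peptide effect between the sexes were tested in a fit with 6 cells of group and sex. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived as the fold change over the square root of the F statistic and are approximate. Expression levels are given in CPM, counts scaled to a common TMM-adjusted library size, as means with SD over mice. For genes with 1 to 3 counts over all wild-type libraries a ratio with a 95% exact binomial interval is given, and for genes with 0 counts there a bound against a floor of 3 counts over the group. These intervals cover counting error only.

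43 gene lists for brain cell types, regions and pathways were written before the data were examined, as were the contrasts, the model and most of the alternatives. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the 43 lists. The same lists were tested with a correlation estimated per list and with fry, whose p asks whether the members move on balance 1 way without setting them against other genes. For each list the mean log2 CPM of its members was taken as a score per mouse, and groups were compared with a two-sided exact permutation test, whose inversion gave a 95% interval and whose p was adjusted over the 43 lists. Some lists share members, such as Cd68 in the microglial and lysosomal lists, and nearly all lists hold genes that brain tissue expresses.

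Genes named in the text were chosen by a fixed rule. For each contrast of groups it takes the 12 called genes with the highest and the 12 with the lowest log2 fold change among those with a mean of at least 1 CPM and an established symbol. It adds up to 4 members per list by lowest p, App and Thy1, and the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Where fewer than 10 genes pass, it takes all of these and the 5 next by p. Any gene outside this rule is named as chosen after its values were seen.

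The procedure was tested on simulated counts, with 50 genes changed at each of 4 fold sizes. They were drawn from each gene's mean over all libraries, its estimated spread and the real library sizes. At a 2-fold change, 60% of the changed genes were recovered for Tg-SwDI PBS against wild type (18470 genes) and 60% for D4F against PBS (18437 genes), and at a 4-fold change 82% and 84%. There were 3 false calls in each of these simulations. No simulated library was made to stand apart from the rest, so these shares need not hold for the real contrasts. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, no sex term, a block for the replicate label, fits with only the compared groups, each sex alone, the animal number series as a covariate, another placing of 1 mouse with conflicting labels, and the omission of each library in turn. The omission of the libraries WT F1 and D4F F3 together, and limma voom with sample weights, were added after seeing the data. Replicate labels (F1, F2, M1 and so on) are shared between groups but do not pair the mice: the median correlation of the 13 same-label pairs, after removal of group and sex means, was -0.0706, against 0.0377 for other pairs across groups. The models are therefore unpaired, and the replicate block stands as an alternative. All per-sample columns of the count table were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.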

Results

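Messenger RNA was measured in the brains of 15 mice, 7 females and 8 males. Of these, 4 were wild type (2 females, 2 males), 5 were Tg-SwDI mice given PBS (2 females, 3 males) and 6 were Tg-SwDI mice given D4F (3 females, 3 males), after 12 weeks of daily treatment. Tg-SwDI mice carry a human amyloid precursor protein transgene with the Swedish, Dutch and Iowa mutations and gather amyloid along brain microvessels. 4F, labelled D4F here, is a peptide made to mimic apolipoprotein A-I, the main protein of high-density lipoprotein. Total counts per library were 25618248 to 32711189 in wild type, 27256821 to 36333318 in the PBS group and 26513146 to 35567424 in the D4F group. The wild-type mice carry no treatment label and have animal numbers outside the ranges of the Tg-SwDI mice, so genotype, cohort and vehicle cannot be told apart. Mouse D4F F1 is D4F by its title and description but PBS by its treatment tag, and was kept in the D4F group. The Tg-SwDI mice were grouped here into animal number series A, B and C, which are runs of close animal numbers. No label names these series or says that they are cohorts or batches.

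Sex-linked genes matched the label in 15 of 15 libraries. Xist, the RNA of X inactivation, was at 270 to 606 CPM in females and at most 0.130 CPM in males, and the Y-linked Ddx3y was at 25.8 to 33.6 CPM in males and at most 0.185 CPM in females. A pair of libraries stood apart from the rest. In D4F F3, mitochondrial transcripts held 23.8% of counts against 7.87% to 10.2% in the other libraries, and its median correlation with the other libraries was 0.943. In WT F1 that correlation was 0.954, against at least 0.972 for the other 13, and 21465 genes were detected against 23261 to 23575 in the other wild-type mice.

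The comparison of Tg-SwDI PBS with wild type asked which transcripts differ between these groups. Amyloid itself was not measured in these data. Genes of activated microglia were far higher in the Tg-SwDI brain. Cst7 (ENSMUSG00000068129, GRCm38 chromosome 2, 150570415 to 150578944), which encodes the protease inhibitor cystatin F, went from 0.194 ± 0.0715 CPM (SD, n = 4) to 156 ± 42.7 CPM (n = 5), a log2 fold change of 9.69 ± 0.40 (SE). Itgax, the CD11c integrin subunit, rose by 8.06 ± 0.40 and Clec7a, the receptor Dectin-1, by 6.57 ± 0.34 on the log2 scale. Gfap, the filament protein of astrocytes, rose from 465 ± 28.2 to 1886 ± 453 CPM, and C1qa, a chain of the complement initiator C1q, from 102 to 484 CPM. Of 18736 genes, 547 were higher and 19 lower (edgeR, 2196 at an unadjusted p under 0.05), and 400 of the higher and 8 of the lower genes changed more than 2-fold. The balance of directions depended on the libraries that stood apart: without WT F1 and D4F F3, 971 genes were higher and 924 lower (557 of the 566 included).

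The 12 largest rises also included the following genes. Pdcd1, the checkpoint receptor PD-1, rose by 5.23 ± 0.47, the Src-family kinase Fgr by 5.09 ± 0.41, the chemokine Ccl3 by 4.86 ± 0.37 and Tnfsf8, the CD30 ligand, by 4.69 ± 0.67 on the log2 scale, each with n = 4 and 5. Several had almost no counts in wild type. Atp6v0d2, a proton pump subunit, was 282 times as high in Tg-SwDI PBS (95% interval 77.9 to 2330, 2 wild-type counts in all). The corresponding ratio was 141 (47.9 to 684) for the hydroxycarboxylic acid receptor gene Hcar2 with 3 counts, 112 (30.9 to 933) for the protease gene Ctse and 102 (27.8 to 842) for the lectin receptor gene Klrb1b with 2 counts each. Cd200r4, with 0 wild-type counts, was at least 62.6-fold higher against a floor of 3 counts over the group.

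Microglial lists rose as groups. Of 22 measured disease-associated microglia genes 21 rose (22 when adjusted over the list alone), with a median log2 fold change of 2.90. The test of this list held with both correlations (camera adjusted p = 1.12e-54; adjusted p = 0.0185 with an estimated correlation). Besides Cst7, Itgax and Clec7a, the chemokine Ccl6 rose by 4.40 ± 0.28. Homeostatic microglia genes rose as well, in 12 of 16 members (14 when adjusted over the list alone; adjusted p = 1.05e-20, and adjusted p = 0.0521 with an estimated correlation). Examples are Fcrls at 2.01 ± 0.17 and Olfml3 at 1.73 ± 0.18 on the log2 scale. Lysosomal genes rose in 12 of 19 members (12 when adjusted over the list alone; adjusted p = 9.2e-16; adjusted p = 0.0455 with an estimated correlation), among them Cd68 by 3.02 ± 0.22 and the cathepsin genes Ctsz by 2.26 and Ctss by 2.08. Complement genes rose in 11 of 16 members (11 when adjusted over the list alone; adjusted p = 1.34e-16; adjusted p = 0.0455 with an estimated correlation), with C1qa at 2.30 ± 0.23 and Itgb2, a subunit of complement receptors, at 2.05 ± 0.22.

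**Figure D1:**
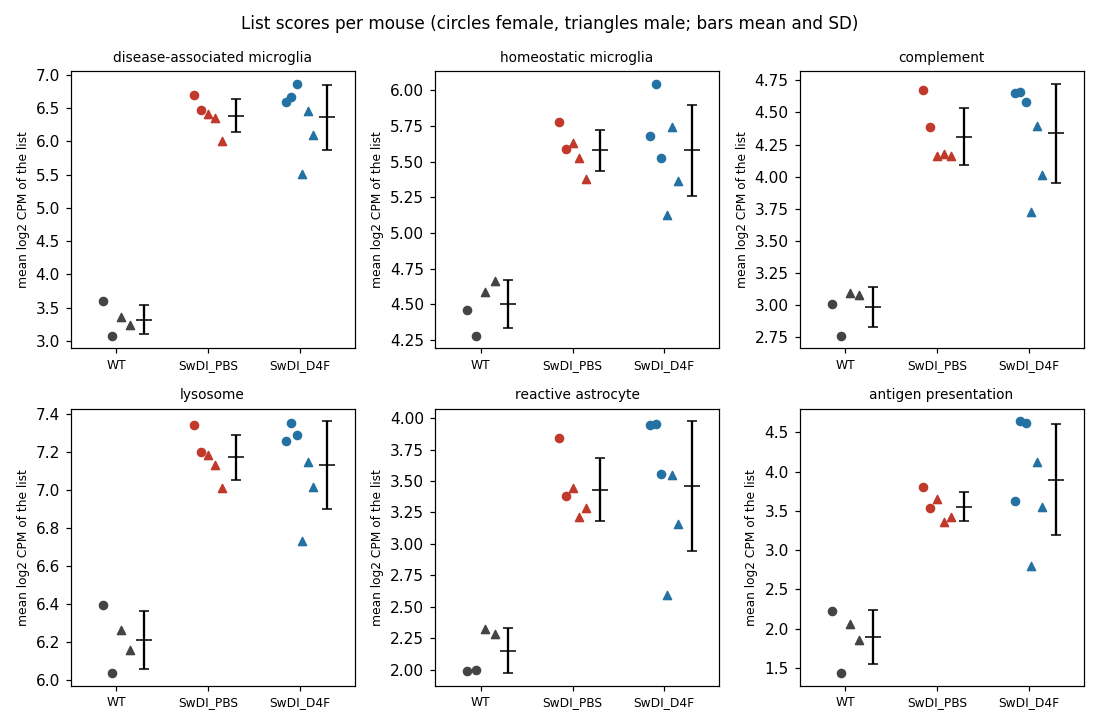
List scores (mean log2 CPM of the members, vertical axis) per mouse in wild type (n = 4), Tg-SwDI PBS (n = 5) and Tg-SwDI D4F (n = 6), for 6 lists; circles are females, triangles males, black bars the mean and SD. The disease-associated microglia score is higher in both Tg-SwDI groups than in wild type. Its D4F minus PBS difference is -0.03 over all mice, -0.37 within animal number series A and -0.18 within series C (1 D4F mouse).

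Antigen presentation, interferon and astrocyte genes also rose against wild type. In the antigen presentation list 11 of 16 members rose (14 when adjusted over the list alone; adjusted p = 1.79e-17, and adjusted p = 0.0887 with an estimated correlation). Cd74, the class II invariant chain, went from 3.39 to 46.6 ± 11 CPM, and the class II genes H2-Aa and H2-Ab1 rose by 3.33 ± 0.54 and 3.25 ± 0.51 on the log2 scale. The interferon list rose with 5 of 20 members called (14 when adjusted over the list alone; adjusted p = 8.72e-10, and adjusted p = 0.245 with an estimated correlation), led by Ifi27l2a at 2.09 ± 0.44. In the cytokine and inflammasome list 5 of 16 rose (9 when adjusted over the list alone; adjusted p = 5.58e-09, and adjusted p = 0.0521 with an estimated correlation), with the receptor Tlr2 at 2.93 ± 0.36 and the cytokine Tgfb1 at 1.80 ± 0.19. Reactive astrocyte genes rose in 8 of 16 members (11 when adjusted over the list alone; adjusted p = 2.66e-13, and adjusted p = 0.0521 with an estimated correlation), Gfap by 2.03 ± 0.19 and the protease inhibitor Serpina3n by 1.77 ± 0.20. Of 14 general astrocyte markers only Sox9 rose, by 0.49 ± 0.12 (2 when adjusted over the list alone; list adjusted p = 0.00672, and adjusted p = 0.282 with an estimated correlation). Border macrophage genes rose with 1 of 10 members called, the mannose receptor gene Mrc1 at 1.02 ± 0.27 (5 when adjusted over the list alone; adjusted p = 0.00035, and adjusted p = 0.274 with an estimated correlation).

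Lipid lists rose as well. In the lipoprotein and cholesterol transport list 5 of 22 members rose (7 up and 1 down when adjusted over the list alone; adjusted p = 0.00123, and adjusted p = 0.074 with an estimated correlation). Apoe, the main brain apolipoprotein, went from 2056 ± 476 to 3438 ± 520 CPM, a log2 fold change of 0.79 ± 0.15, and Ch25h, cholesterol 25-hydroxylase, rose by 2.91 ± 0.36. In the list of oxidized lipids and eicosanoids 3 of 13 rose (7 when adjusted over the list alone; adjusted p = 6.51e-06, and adjusted p = 0.117 with an estimated correlation), Alox5, 5-lipoxygenase, by 2.37 ± 0.30. Cholesterol synthesis rose as a list with 1 of 22 members called, Nsdhl at 0.52 ± 0.12 (2 when adjusted over the list alone; adjusted p = 0.00037, and adjusted p = 0.147 with an estimated correlation). Antioxidant genes (1 of 16, Hmox1 at 0.73 ± 0.18; 4 when adjusted over the list alone; adjusted p = 0.0103) and iron and haem genes (2 of 11, with the ferritin gene Ftl1 at 0.56 ± 0.11; 4 when adjusted over the list alone; adjusted p = 0.0277) rose as lists, each with adjusted p = 0.147 with an estimated correlation. Both lost the call without WT F2 (adjusted p = 0.0752 and 0.0828).

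Vessel wall and meningeal genes were higher in Tg-SwDI PBS too. In the pericyte and smooth muscle list the contractile genes Acta2 (17.5 ± 6.56 to 34.7 ± 8.30 CPM) and Tagln (8.87 to 22.4 CPM) rose, 2 of 15 members (6 when adjusted over the list alone; list adjusted p = 0.000939, and adjusted p = 0.282 with an estimated correlation). Of 15 meningeal fibroblast genes 2 rose, Slc47a1 by 2.06 ± 0.42 and the proteoglycan gene Bgn by 0.95 ± 0.21 (10 when adjusted over the list alone; list adjusted p = 4.54e-07, and adjusted p = 0.232 with an estimated correlation). The choroid plexus list also rose with 0 of 13 members called (also 0 when adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.519 with an estimated correlation), and its call was lost without WT M2 (0.159). Its score ranged from 1.5 to 6.67 over the mice.

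Among the 19 genes called lower with all libraries, against 924 without WT F1 and D4F F3, Ngef, a neuronal guanine nucleotide exchange factor, fell from 90.9 ± 20.1 to 31.8 ± 7.40 CPM (log2 fold change -1.54 ± 0.19). The activity-regulated genes Arc and Fosb had log2 fold changes of -0.99 ± 0.19 and -0.98 ± 0.19, and 2 of 13 immediate early genes fell (5 when adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.282 with an estimated correlation). These 3 genes kept the call without any 1 library, whereas the other 9 of the 12 largest falls lost it in at least 1 omission. Of those, Egfl6 (-0.96) lost it without WT M2 (adjusted p = 0.0694) and Spry4 (-0.51) without PBS M3 (0.0549), while Dnd1, Tnfrsf25, Hif3a, Crybb3, Stac, Slc39a2 and Nrarp each lost it in 5 to 8 omissions, which between them took in every wild-type and PBS library (highest adjusted p 0.0958 to 0.14). Synaptic genes were lower as a list, with 20 of 21 members negative (median -0.12, 0 called, 0 when adjusted over the list alone; adjusted p = 0.00289, and adjusted p = 0.282 with an estimated correlation). The lowest p among them belonged to members such as the receptor subunit genes Grin1 at -0.24 and Gria1 at -0.22.

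Other lists that were lower lost the call when single libraries were left out. Inhibitory neuron genes (median -0.20, adjusted p = 0.0149) lost the call without WT F1 (0.134), as did immediate early genes (0.0659). Heat shock genes (-0.13, adjusted p = 0.0126) lost it without WT M1 (0.157), and the erythrocyte list, whose 4 tested members are haemoglobin genes (-1.81, adjusted p = 0.0118, 4 lower when adjusted over the list alone), without WT M1 (0.157) or WT M2 (0.323). The glucocorticoid list (-0.24, adjusted p = 0.0239) lost it without WT F2 (0.0895), WT M1 (0.255) or PBS M2 (0.104). The circadian list (-0.08, adjusted p = 0.0483) lost it without WT F2, WT M1, WT M2, PBS M2, PBS M3, D4F F2, D4F F3 or D4F M1 (0.0517 to 0.134). With an estimated correlation the adjusted p was 0.282 for inhibitory neurons and erythrocytes and 0.316 for heat shock, circadian and glucocorticoid genes. The other 18 lists did not pass (adjusted p = 0.053 to 0.893): amyloid precursor processing and clearance, endothelial and blood-brain barrier, endothelial activation, vascular basement membrane, myelin, oligodendrocyte precursors, excitatory neurons, unfolded protein response, oxidative phosphorylation, ribosome, lymphocytes, neutrophils, ependyma, striatum, hippocampus, thalamus, hypothalamus and cerebellum. The amyloid precursor processing list had a median of -0.04 and a mean of 0.03.

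In all, 25 of 43 lists passed (18 higher, 7 lower), 3 of them with an estimated correlation and 16 with fry. By the exact permutation test of the scores 14 lists passed. None of the 7 lower lists did (adjusted p = 0.233 to 0.437). Of the higher lists, pericytes and smooth muscle, antioxidant, iron and haem, and choroid plexus did not (adjusted p = 0.0802 to 0.341). Without WT F1 and D4F F3, which brought the gene count to 1895, 25 lists passed, 21 of them as before, with inhibitory neurons, immediate early genes, heat shock and erythrocytes no longer past the threshold. Without WT F2 364 genes were called.

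The mouse gene Thy1, whose promoter drives the transgene, was at 1158 ± 143 CPM in wild type, 3234 ± 427 CPM in Tg-SwDI PBS and 3547 ± 1037 CPM with D4F (Tg-SwDI PBS against wild type 1.52 ± 0.15, adjusted p = 1.18e-05). Mouse App was at 1234 ± 149, 1123 ± 94.2 and 1076 ± 217 CPM and did not pass (adjusted p = 0.73). How reads from the human sequence were assigned is not given in the sources used here.

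**Figure D2:**
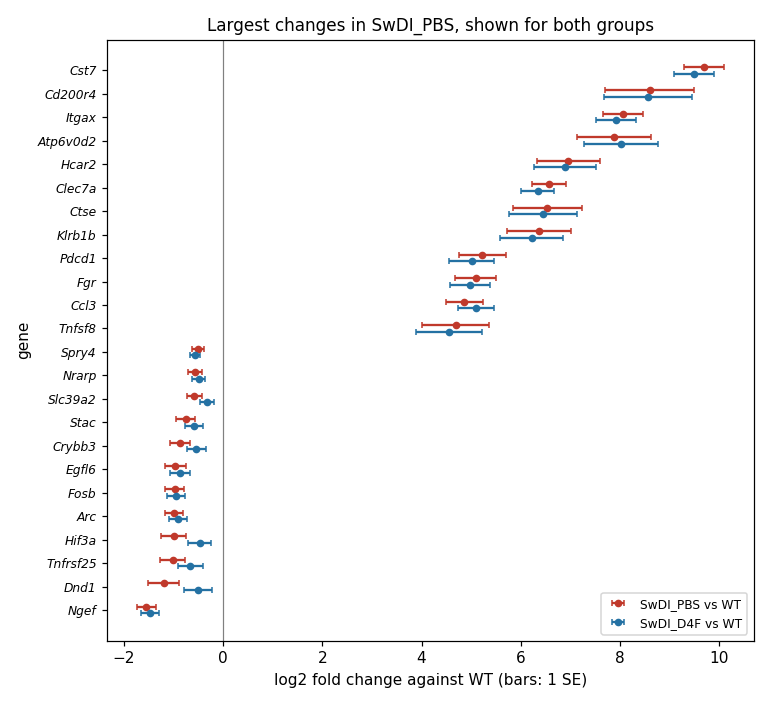
Log2 fold change against wild type, with 1 SE to each side, of the 12 genes with the largest rise and the 12 with the largest fall in Tg-SwDI PBS, for the PBS (n = 5) and D4F (n = 6) groups against wild type (n = 4). Cst7 stands at 9.69 in PBS and 9.49 in D4F, and Ngef at -1.54 and -1.48.

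The comparison of D4F with PBS asked what the peptide changes in Tg-SwDI brain. Genes of activated microglia did not differ past the threshold: Cst7 was at 145 ± 56.0 CPM (n = 6) with D4F and 156 ± 42.7 CPM (n = 5) with PBS, and Gfap at 1927 ± 593 against 1886 ± 453 CPM. Contractile genes of vascular smooth muscle were lower with D4F and near their wild-type level, a difference called with DESeq2 but not with edgeR. Acta2, smooth muscle actin, was at 17.3 ± 3.58 CPM against 34.7 ± 8.30 with PBS and 17.5 ± 6.56 in wild type, and Myh11, smooth muscle myosin, at 16.6 ± 3.99 against 34.2 ± 9.42 and 18.4 ± 7.29 CPM. Acta2 and Myh11 are shown because their p values were among the lowest of this comparison. The comparison with wild type uses the same PBS mice, so high values in these mice by chance would give the same pattern. A return to the wild-type level was therefore not tested. Interferon response genes were higher in 3 of the 6 D4F mice.

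No single gene passed with edgeR: 0 of 18736 were called, with 416 at an unadjusted p under 0.05 where 936.8 would be given by chance, and a lowest adjusted p of 0.456. RLE scaling (411 unadjusted) and limma voom with sample weights (672 unadjusted) also gave 0, while DESeq2 called 4 (502 unadjusted) and a fit without the filter on low counts 169 (1331 unadjusted). The DESeq2 genes were the predicted gene Gm43305, higher at 1.22 (adjusted p = 0.000166), and Acta2 at -1.0 (0.0345), Tagln at -0.98 (0.0471) and Myh11 at -1.04 (0.0482), lower. In edgeR these and Lmod1, a smooth muscle actin nucleator at -1.05 ± 0.25, had the 5 lowest p values and did not pass. Acta2, Tagln and Lmod1 lay below all PBS mice in 6 of 6 D4F mice and Myh11 in 5 of 6, and Gm43305 lay above all PBS mice in 6 of 6. The edgeR adjusted p was 0.456 for Gm43305 and 1 for Acta2, Tagln and Myh11. In the omissions of single libraries with the largest change it was 0.375 for Gm43305, Acta2 and Tagln and 0.765 for Myh11.

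As groups, vessel-associated genes were lower with D4F by camera with a correlation of 0.01. The lists of this paragraph did not pass with fry (adjusted p = 0.5 to 0.851) or the exact permutation test (adjusted p = 0.386 each). Other splits of these mice passed up to 21 lists by the same camera test. The pericyte and smooth muscle list fell (13 of 15 members negative, median -0.33; camera adjusted p = 4.8e-09, and adjusted p = 0.316 with an estimated correlation), with 0 members called over all genes and 5 lower when adjusted over the list alone. Its score differed by -0.42 (95% interval -0.65 to -0.17 from the exact permutation test, p = 0.0152, adjusted 0.386). The endothelial and blood-brain barrier list fell (13 of 15 negative, median -0.35; adjusted p = 6.82e-08, and adjusted p = 0.344 with an estimated correlation), with 0 called and 7 lower when adjusted over the list alone. For its score the difference was -0.29 (exact permutation interval -0.59 to 0.01, p = 0.0628, adjusted 0.386). Members with the lowest p were the VE-cadherin gene Cdh5 at -0.70 ± 0.22, Pecam1 at -0.56 ± 0.17 and the efflux pump gene Abcb1a at -0.53 ± 0.16. Meningeal fibroblast genes fell as a list too (15 of 15 negative, median -0.52; adjusted p = 6.36e-11, and adjusted p = 0.339 with an estimated correlation), with Fmod at -1.0 and Ogn at -0.92 and 0 called over all genes or when adjusted over the list alone. Vascular basement membrane genes, such as Nid1 at -0.63 and the fibronectin gene Fn1 at -0.57, also fell as a list (median -0.22; adjusted p = 0.00163, and adjusted p = 0.601 with an estimated correlation). Within animal number series A (2 PBS and 3 D4F mice) and series C (3 PBS and 1 D4F mouse) the pericyte and smooth muscle score differed by -0.53 and -0.31, the endothelial score by -0.30 and -0.32 and the meningeal score by -0.77 and -0.12.

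Interferon response genes rose as a list with D4F (20 of 20 members positive, median 0.68, 1.6-fold; adjusted p = 4.65e-13, and adjusted p = 0.344 with an estimated correlation), with 0 called over all genes and 7 higher when adjusted over the list alone. Isg15, an interferon-induced ubiquitin-like protein, was at 3.48 ± 2.78 CPM against 1.09 ± 0.637 with PBS, and the interferon regulator Irf7 at 11.9 ± 8.79 against 4.35 CPM. The score lay above all PBS mice in 3 of 6 D4F mice, F2, F3 and M3, and differed by 0.65 (exact permutation interval -0.25 to 1.57, adjusted p = 0.543). Within series A the difference was -0.07, and within series C it was 0.90 with 1 D4F mouse, so the rise did not hold within series A. D4F mice F2 and F3 form series B, which has no PBS mouse. Antigen presentation genes rose as a list (16 of 16 positive, median 0.40; adjusted p = 4.58e-05, and adjusted p = 0.666 with an estimated correlation), with differences of -0.21 in series A and 0.12 in series C.

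Weaker list differences rested on single libraries. Choroid plexus (median -0.92, adjusted p = 0.00308), border macrophages (-0.41, 0.011), cholesterol synthesis (-0.07, 0.011) and endothelial activation (-0.31, 0.0134) fell as lists, and cytosolic ribosome (0.15, 0.00105), hypothalamus (0.62, 0.013), myelin (0.13, 0.0172), heat shock (0.07, 0.0499) and neutrophils and monocytes (1.05, 0.0499) rose. None of these held with an estimated correlation (adjusted p = 0.807, 0.666, 0.535, 0.389, 0.807, 0.316, 0.808, 0.807 and 0.501 in that order). Each lost the call without at least 1 library. Myelin lost it without D4F F3 (0.927), PBS M1 (0.0527) or PBS M2 (0.12), and ribosome without D4F F3 (0.45) or PBS F2 (0.269); mitochondrial transcripts were high in D4F F3. Choroid plexus lost it without PBS F1 (0.113), D4F F2 (0.101) or D4F F3 (0.109), border macrophages without PBS F1 (0.0992), PBS M1 (0.0667) or D4F M1 (0.167), and cholesterol synthesis without PBS M1 (0.161). Endothelial activation lost it without PBS M1, PBS M3, D4F M1 or D4F M2 (0.0504 to 0.0938) and hypothalamus without PBS M1, D4F F2, D4F F3 or D4F M1 (0.0983 to 0.183). Heat shock lost it in 7 omissions, PBS F2, M1 and M3 and D4F F1, F2, M1 and M2 (up to 0.301), and neutrophils in 10, all but WT M1, WT M2, PBS F1, D4F M1 and D4F M3 (up to 0.171). The score difference kept its pooled sign for 11 of the 15 passing lists within series A and for 11 within series C, and for choroid plexus it was 1.33 in series A and -1.64 in series C. In all 15 of 43 lists passed (7 higher, 8 lower), and 9 without PBS M1. None passed with an estimated correlation, with fry or with the adjusted permutation test.

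**Figure D3:**
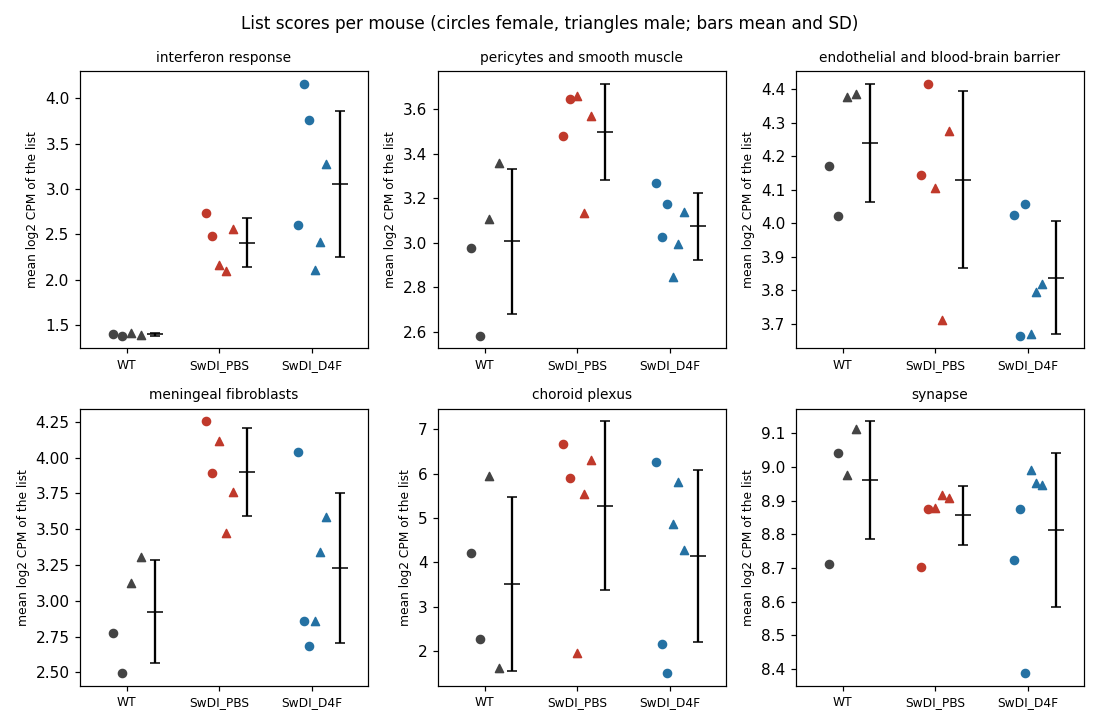
List scores (mean log2 CPM of the members, vertical axis) per mouse in wild type (n = 4), Tg-SwDI PBS (n = 5) and Tg-SwDI D4F (n = 6), for 6 lists; circles are females, triangles males, black bars the mean and SD. The interferon score of D4F mice F2 (4.16), F3 (3.76) and M3 (3.28) is above the PBS range of 2.10 to 2.73, and choroid plexus scores spread from 1.5 to 6.67.

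Other lists that were higher in Tg-SwDI PBS than in wild type did not pass between D4F and PBS. The score difference was -0.03 for disease-associated microglia (exact permutation interval -0.58 to 0.50), 0.00 for homeostatic microglia (-0.36 to 0.36), 0.03 for reactive astrocytes (-0.57 to 0.57), 0.03 for complement (-0.43 to 0.48), -0.04 for the lysosome (-0.31 to 0.20) and 0.00 for lipoprotein and cholesterol transport (-0.12 to 0.12). A difference inside these intervals was not excluded. The intervals do not allow for animal number series. Within series A (3 D4F mice) the differences were -0.37, -0.19, -0.28, -0.16, -0.22 and -0.03 in the order above. Within series C (1 D4F mouse) they were -0.18, -0.13, -0.13, -0.23, -0.10 and -0.12. D4F mice F2 and F3 form series B, where series and peptide cannot be told apart. Of the 547 genes higher in Tg-SwDI PBS than in wild type, 272 had a positive and 275 a negative log2 fold change with D4F. Across the 18736 genes the correlation of the D4F effect with the transgene effect was -0.274 (Spearman -0.273). Genes are not independent replicates, and both effects share the PBS mice, which gave -0.495 ± 0.011 (SD) in 20 simulations without any effect. Those simulations lack the transgene effect, which alters the spread that r is scaled by, so the r values are not alike. The covariance was -0.0435, against -0.0494 ± 0.0019 (SD) in the simulations. With the PBS mice divided between both effects the mean r over 10 divisions was -0.0153, from -0.0747 to 0.125. The mean covariance over these divisions was -0.00198.

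D4F-treated Tg-SwDI mice were set beside wild type to see how far they stand from it. Microglial genes were again far higher, Cst7 by 9.49 ± 0.40 and Itgax from 0.247 to 59.4 ± 19.5 CPM, and interferon genes rose in 16 of 20 members (20 when adjusted over the list alone; adjusted p = 3.31e-20, and adjusted p = 0.0754 with an estimated correlation). Ifi27l2a rose by 3.24 ± 0.44 and Ifit3 by 2.04 ± 0.31. In all, edgeR called 628 genes (601 higher, 27 lower; 2435 at an unadjusted p under 0.05), among them 481 higher and 8 lower that were also called in PBS mice. Both contrasts share the wild-type mice. With these divided, which also leaves 2 per contrast, 157 to 225 genes were higher in both, so how much of the overlap comes from sharing was not separated. Without WT F1 and D4F F3 the count was 1335 (797 higher, 538 lower).

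The vessel genes Flt1, a VEGF receptor, and Abcb1a were lower with D4F than in wild type. Flt1 was at 33.0 ± 2.82 CPM against 57.2 ± 14 (-0.79 ± 0.16, adjusted p = 0.00861) and Abcb1a at 12.2 ± 1.01 against 20.6 CPM (-0.76 ± 0.16, adjusted p = 0.0122; 0.0538 without WT M2). The endothelial and blood-brain barrier list fell, with 15 of 15 members negative and 2 called (adjusted p = 5.58e-07, and adjusted p = 0.153 with an estimated correlation). Immediate early genes fell in 4 of 13 members (adjusted p = 1.19e-05, and adjusted p = 0.154 with an estimated correlation), and Ngef was again lower at -1.48 ± 0.18. In this contrast 26 of 43 lists passed (19 higher, 7 lower), 7 of them with an estimated correlation: disease-associated microglia (0.022), homeostatic microglia, reactive astrocyte, antigen presentation and lysosome (0.0494 each), and complement and cytokines (0.0423 each). By the adjusted permutation test 9 lists passed, and the endothelial list (0.0628), the interferon list (0.0512) and immediate early genes (0.109) did not.

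The genes called between females and males were mainly sex-linked. Xist and Pbdc1, both on the X chromosome, were higher in females, Pbdc1 by 0.71 ± 0.11 (adjusted p = 0.0221). Ddx3y, Eif2s3y, Kdm5d, Uty and the Y-linked Gm29650 were lower, as was 5830487J09Rik (-2.55, adjusted p = 0.0461) on chromosome 5. These 8 genes passed with edgeR, while DESeq2 called 326. At an unadjusted p under 0.05 there were 3602 with edgeR, where 936.8 would be given by chance. The libraries that stood apart, WT F1 and D4F F3, are both from females, so this excess cannot be told apart from them. For the difference of the transgene effect between the sexes edgeR called 0 genes (1459 unadjusted) and DESeq2 10, and for the difference of the D4F effect both called 0 (533 unadjusted with edgeR).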

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

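Tests chosen after the result was seen were those without D4F F3 for the vessel lists and those on animal number series C and B for the interferon list, and the omissions of libraries for the differences between the sexes. A single mouse far from the rest of its group, by Dixon's criterion at 95%, was found 13 times in 144 groups of values, where chance gives about 1 in 20, or 7.2.

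D4F F3 carried 7 of these. Its mitochondrial share was 23.8% (other D4F mice 7.87% to 9.69%), its TMM factor 0.844 (0.998 to 1.03) and its slope of log2 counts on gene length -0.33 (-0.0596 to 0.0515). Its list scores were 7.65 for astrocyte markers (7.97 to 8.14), 5.99 for amyloid precursor processing (6.21 to 6.28), 7.65 for myelin (6.82 to 7.07) and 7.45 for oxidative phosphorylation (6.79 to 6.97). WT F1 had 21465 genes detected (23261 to 23575) and scores of 5.09 for cholesterol synthesis (4.88 to 4.91) and 8.39 for the ribosome (7.44 to 7.59). Though not flagged, its slope on gene length was -0.26 (0.051 to 0.116) and its oxidative phosphorylation score 7.50 (6.67 to 6.89). The synapse score was 8.70 in PBS F1 (8.87 to 8.92). In PBS M1 the immediate early score was 5.06 (4.52 to 4.67) and the choroid plexus score 1.95 (5.54 to 6.67).

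Between the sexes the transgene effect differed for 13 lists and the D4F effect for 9, by a test of the difference itself, with 0 for either by an estimated correlation or fry. As score differences, the transgene effect was higher in females than in males by 0.87 for meningeal fibroblast genes (adjusted p = 0.151 without WT F2) and by 1.25 for border macrophage genes. For oxidative phosphorylation the difference was -0.45, but -0.15 (adjusted p = 0.03) without WT F1, which stands apart, and -0.76 without WT F2. The number of these lists was 24 without WT F1, 4 without WT F2, 8 without PBS F1 and 21 without PBS F2; where 1 wild-type or PBS female was left, it was assumed to vary like the other mice. The D4F effect was higher in females by 0.57 for interferon genes, with 0.25 without D4F F2 (adjusted p = 0.313), 0.33 without D4F M1 (adjusted p = 0.0689), 1.02 without D4F F1 and 0.91 without D4F M3. It was -3.37 for choroid plexus genes (-2.05 without PBS M1), and the number of these lists was 4 without PBS F2, 4 without D4F F2 and 14 without D4F M2. Of the 3 D4F females, F2 and F3 form series B, which has no PBS mouse, so these differences of the D4F effect cannot be told apart from series: their interferon scores were 4.16 and 3.76 and their choroid plexus scores 2.15 and 1.5, against 2.61 and 6.26 in F1.

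Vessel, smooth muscle, meningeal and choroid plexus lists lower with D4F than with PBS form the first pattern weighed. The library D4F F3 as its whole cause is argued against, since without it 6 of the 7 lists stayed lower and choroid plexus (adjusted p = 0.109) did not. A different share of meninges in the tissue cannot be told apart from an effect of the peptide: with the meningeal score as a covariate 2 of the other 6 lists stayed lower, with score differences going from -0.42 to -0.19 for pericytes and smooth muscle (adjusted p = 0.00335) and from -0.30 to -0.14 for the endothelium (0.00709). The border macrophage difference turned from -0.34 to 0.27 (adjusted p = 0.0964); the covariate itself differs between the groups, which keeps this open. Chance is not excluded either: of 100 splits of these mice, the real one among them, 12 passed at least as many lists. A lower vessel wall expression with D4F, such as less smooth muscle actin, may remain as a hypothesis.

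The interferon list higher with D4F is the next pattern. Its rise does not come from D4F F3 alone, since the adjusted p without that library was 1.14e-09. Animal number series C as the source is argued against by the PBS mice, where series C minus series A was -0.07 (-0.0687). Series B stays open: its D4F mice scored 1.36 above the other D4F mice, and with no PBS mouse in that series it cannot be told apart from the peptide. Chance is not excluded, as the exact permutation test of the score gave an adjusted p = 0.543. An effect of the peptide in some mice may remain as a hypothesis.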

How the results depend on the processing

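Tests added after seeing the data were those without WT F1 and D4F F3, those with voom and the omissions for lists that differed between the sexes. No named gene that was called changed sign, and no list that passed did so in the opposite direction, under the settings below. Between D4F and PBS the uncalled App (-0.08 to 0.04), Thy1 (-0.02 to 0.13), Xist (-0.15 to 0.03), Ddx3y (-0.05 to 0.11) and Uty (-0.10 to 0.10) changed sign over single omissions. Causes of the changes were not tested. Fits of 1 sex hold fewer mice, and without the filter 31902 genes were tested. For Tg-SwDI PBS against wild type (566 genes) the count was 1110 without the filter (546 shared), 160 in females alone (158 shared), 1073 in males alone (362 shared), 1895 without WT F1 and D4F F3 (557 shared), 1285 with voom (551 shared) and 364 (without WT F2) to 544 over single omissions. It was 841 with DESeq2, 581 with the replicate block and 687 with D4F F1 counted as PBS. Ranges of called genes and passing lists for contrasts of groups cover only omissions of libraries from the compared groups and of D4F F1. For Tg-SwDI PBS against wild type the omission of D4F F3 alone is thus not among them. For D4F against PBS (0 genes) the count was 4 with DESeq2 and 169 without the filter. It was 0 with the replicate block, each sex alone, the number series, D4F F1 counted as PBS, voom and RLE. It was also 0 in every omission of 1 PBS or D4F library and in that of WT F1 and D4F F3. For D4F against wild type (628) it was 945 with DESeq2, 1078 without the filter, 304 in females, 290 in males, 1335 without WT F1 and D4F F3, and 421 to 674 over single omissions. Females against males (8) gave 326 with DESeq2, 1488 without the filter and 12 without WT F1 and D4F F3. The transgene-by-sex term (0) gave 10 with DESeq2 and 342 without the filter, and the D4F-by-sex term (0) 76 without the filter. Lists for Tg-SwDI PBS against wild type (25) numbered 3 with an estimated correlation, 16 with fry and 25 to 30 over single omissions; of the 25, 9 were lost in at least 1 omission, 4 without WT F1 and D4F F3 and 2 without the sex term. Lists for D4F against PBS (15) numbered 0 with an estimated correlation, 0 with fry, 9 without PBS M1 and up to 19 over single omissions, and 9 of the 15 were lost in at least 1 omission. With the replicate block 11 passed, myelin (0.954), ribosome (0.486), neutrophils (0.0817) and choroid plexus (0.12) being lost. Without WT F1 and D4F F3 10 passed, the same 4 (0.94, 0.218, 0.144 and 0.174) and hypothalamus (0.0666) being lost. With D4F F1 counted as PBS 12 of the 15 stayed, without heat shock (0.364), neutrophils (0.442) and hypothalamus (0.0949), and 3 others came in; without the sex term 13 passed, heat shock (0.0515) and neutrophils (0.0534) being lost. Lists that differed between the sexes numbered 4 to 24 over single omissions and 20 without WT F1 and D4F F3 for the transgene effect (13), and 4 to 14 and 12 for the D4F effect (9). The correlation of both effects (-0.274) was -0.0153 with the PBS mice divided, -0.207 at 5 CPM or more, -0.26 without the sex term, -0.0809 over called genes, -0.299 with D4F F1 counted as PBS, -0.293 without D4F F1 and -0.316 without WT F1 and D4F F3. The 12 largest rises and 12 largest falls in each contrast with wild type make 48 gene and contrast pairs, all called in the analysis used here; of these pairs 48 were called with DESeq2, 38 without the sex term, 43 with the block and 37 (without WT M2) to 47 over single omissions. Depth limits the genes with 0 to 3 wild-type counts, whose ratios have wide intervals.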

Other observations

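Tests of the Thy1 relation with sex removed, with the animal number series removed, and without D4F F3 with group removed, were chosen after the result was seen, as were the count over abundant genes with called genes included and the count of splits for the lists of D4F against wild type.

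Choroid plexus and ependymal genes varied from mouse to mouse within every group. Ttr, the transthyretin gene of choroid plexus, was at 1515 ± 1937 CPM in wild type (SD, n = 4), 4320 ± 2876 in Tg-SwDI PBS (n = 5) and 2365 ± 2574 with D4F (n = 6). The choroid plexus score was 1.62 to 5.94 in wild type, 1.95 to 6.67 in PBS mice and 1.5 to 6.26 in D4F mice. Ttr was chosen after its values were seen.

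Across the 11 Tg-SwDI mice, Thy1 (log2 CPM) rose with the disease-associated microglia score (r = 0.833, permutation p = 0.00205; Spearman rho = 0.891, permutation p = 0.00052; 1e+05 permutations), and without the 2 mice farthest from the median Thy1 r was 0.868 (9 mice, permutation p = 0.00215). Sex of the mice as the source is argued against by r = 0.656 with sex removed (permutation p = 0.0255), and D4F F3 and treatment by r = 0.819 without them (permutation p = 0.00435). Composition shared by abundant genes cannot be told apart: 1.29% of 2091 other genes of at least 100 CPM (27 genes) had an r as high, where under 1% had been set to argue against it. A first count, which left out genes called between Tg-SwDI PBS and wild type, gave 4 of 2055. The animal number series is argued against by r = 0.865 with series removed (permutation within series, p = 0.00165); each series holds fewer than 6 Tg-SwDI mice, so no r is given for 1 series alone. A candidate explanation is that Thy1 reads report expression of the transgene cassette, and that mice with more of it have more activated microglia; this is a hypothesis found and tested on the same mice.

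Other splits of the same mice into groups of the same sizes were drawn, 100 per contrast with the real one among them. Chance can be excluded for the genes of Tg-SwDI PBS against wild type (566 genes, 1 split as large, highest other 0) and of D4F against wild type (628, 1 split, highest other 30). For females against males (8, 1 split, highest other 1) the splits say little of chance. Most of these genes, Xist and the Y-linked ones, are almost absent from 1 sex, so splits that mix the sexes could hardly call them. For D4F against PBS the real count was 0 genes, so that all 100 splits give as many by construction (highest other 5), which says nothing of chance. For the number of lists that passed, no other split drawn reached the count of D4F against wild type (26 lists, 1 split, highest other 24). The margin is small, and the split with 24 lists kept D4F F1, F2, F3, M1 and M2 together, with WT M1. Chance cannot be excluded for D4F against PBS (15 lists, 12 splits, highest other 21). By the rule set beforehand, under 5 of 100 splits, it is not excluded for Tg-SwDI PBS against wild type either (25 lists, 14 splits, highest other 29). Splits with many lists, such as all wild-type mice with PBS F1 (28 lists), still kept most mice of a genotype together. They therefore carry part of any genotype difference.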
